A study of Mus musculus with 26 samples.

How the data were processed

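Gene expression was measured in the lacrimal glands of male C57BL/6.NOD-Aec1Aec2 mice on 26 Affymetrix arrays, 4 at 4 weeks of age, 6 at 8 weeks, 6 at 12 weeks, 5 at 16 weeks and 5 at 20 weeks. Per the labels, total RNA was isolated with an RNeasy kit and turned into biotinylated cRNA by the manufacturer's standard procedure. Each array was placed in its age group from its title, which also calls it a biological replicate. Whether each replicate is 1 animal or a pool is not given in the sources used here, and neither are dates of dissection, hybridisation or scanning, so p-values measure the spread between these samples.

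The deposited values are a single table of log2 expression for 45101 probe sets on the 26 arrays. RMA and GCRMA, a pair of methods that correct the background, normalise between arrays and summarise the probes of a probe set, are named in the submitters' processing notes without versions or roles, so which of them made these values is not given in the sources used here. Array medians of the deposited log2 values lay between 2.94 and 3.22, and the values were used as they are. Detection calls were not used here, so a gene near the array medians cannot be told from background. A mean under 4.04, which is within 1 log2 unit of the median of those medians, is called near background, and a change from or to it a lower bound. The number of arrays limits the precision.

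Probe sets were named through the platform's annotation table, in which 34958 probe sets had 1 gene symbol, 932 had several and 9211 were not listed. Probe sets with several symbols or none were left out of the gene tests. The 64 control probe sets were not removed as such, so any of them with 1 gene symbol could stand for its gene. Each of the 18194 genes was represented by its probe set with the highest mean over all arrays. A gene was kept if that probe set lay above its array's median on at least 4 arrays, which left 12377 genes.

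Linear models were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean per age over all 26 arrays and no covariate. An F test compared the 5 ages, and contrasts compared 8 with 4, 12 with 8, 16 with 12, 20 with 16 and 20 with 4 weeks. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes kept, and a gene was called changed at an adjusted p under 0.05. Changes are log2 differences, later minus earlier age, with the standard error (SE) of the fit.

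Before the data were examined, 50 gene lists of cell types, pathways and neighbouring tissues were fixed, together with the comparisons, the tests, the rule for naming genes and the other settings to be tried. The lists held 797 genes, of which 707 had a probe set here and 539 were kept. The 47 lists with at least 3 kept genes were tested with camera from limma at its preset correlation between genes of 0.01, and with an estimated correlation beside it, each adjusted over the 47 lists within a comparison. Camera compares a list with all other genes. Members past the gene test were counted over all genes kept and adjusted over the list alone.

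The genes named were taken from those that a fixed rule picked, and not all of the genes picked are described. Per comparison the rule picked the 10 with the highest and the 10 with the lowest log2 change among those called. It also picked up to 4 members with the smallest p of each list described, and the 10 genes with the largest F over all ages. Il2, Il21, Ctla4, Icos, Slc11a1, Chrm3, Aqp5 and Trim21 were added. The study's own description points to these, or they are known from Sjögren's syndrome. A gene outside this rule is said to have been chosen after its values were seen.

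The settings fixed beforehand were quantile normalization, centring of each array on its median, no filter, a stricter filter at the 75th percentile, the mean of a gene's probe sets, leaving out probe sets whose names end in _x_at or _s_at and which can bind related transcripts, eBayes with trend and robust, array weights, a threshold of at least 2-fold, the replicate number as a block, only the arrays of the ages compared, camera with an estimated correlation or on ranks, and leaving out each array in turn. After the data were seen, further fits left out 16 weeks replicate 4 and 20 weeks replicate 1, estimated array weights gene by gene, or added as covariates the spread of each array, the adipose tissue and salivary gland list means, or the difference between the 3' and 5' actin control probe sets.

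The tests were run first on simulated values with the real means and spreads, where a set of genes was changed by known amounts. At 2-fold, 56.7% of changed genes were found for 8 against 4 weeks, 49.3% for 12 against 8, 59.7% for 16 against 12, 37.3% for 20 against 16, 55.2% for 20 against 4 and 58.5% in the F test, with 4 to 10 false calls among 12377 genes. Camera found a list of 16 genes shifted by 1.5-fold in every comparison, and called no other list at the preset correlation. The simulated genes varied independently of each other and no simulated array stood apart. The numbers of false calls therefore do not carry over to the real arrays, where genes vary together.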

Results

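Expression in the lacrimal gland, which secretes the watery part of the tear film, was followed in male C57BL/6.NOD-Aec1Aec2 mice on 26 arrays. This strain carries a pair of NOD-derived regions, Idd3 on chromosome 3 and Idd5 on chromosome 1, in the C57BL/6 background and develops a disease resembling Sjögren's syndrome, an autoimmune disease of tear and salivary glands. The ages stand for stages of that disease in the study's description. Disease has not begun at 4 weeks (n = 4), 8 weeks (n = 6) is pre-clinical, and leukocytes enter the gland from 12 weeks (n = 6). Clinical autoimmunity begins at 16 weeks (n = 5) and secretion has declined at 20 weeks (n = 5). The comparisons ask which genes changed between successive stages and over the whole course. No control strain was analysed here, so a change with age is not separated from a change with disease.

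Correlations between arrays lay between 0.797 and 0.990. Xist, the transcript of the inactive X chromosome, was at 3.00 to 3.91 on all arrays, near the array medians, and the Y-linked Eif2s3y was at 3.97 to 8.10. A pair of arrays stood apart. The SD of all log2 values was 1.36 on 20 weeks replicate 1 and 1.68 on 16 weeks replicate 4, against 1.78 to 2.27 on the other arrays. Their median correlation with the arrays of their own age was 0.869 and 0.921, against 0.956 to 0.986. Markers of neighbouring tissues differed between arrays. The mean of 7 salivary gland genes ranged from 4.56 on 8 weeks replicate 5 to 12.04 on 4 weeks replicate 1. By age it was 8.60, 7.88, 9.54, 7.19 and 8.12 from 4 to 20 weeks. The mean of 6 adipose tissue genes was 3.99 at 4 weeks, 5.51 at 16 weeks and 4.43 at 20 weeks. Its highest values were on 12 weeks replicate 1 (6.77) and 16 weeks replicates 1 (6.91) and 2 (7.58). Neither list passed the camera test in any comparison with all arrays. Without 1 array, the salivary gland list passed at 8 weeks without 4 weeks replicate 2 (adjusted p = 0.0366), and at 12 weeks without 8 weeks replicates 1 (0.0361) and 3 (0.0089) and 12 weeks replicate 3 (0.0198). The adipose tissue list passed at 16 weeks without 16 weeks replicates 3 (0.0298) and 5 (0.0263), and at 20 against 16 weeks without 16 weeks replicates 3 (0.00338), 4 (0.0442) and 5 (0.00494) and 20 weeks replicate 1 (0.0256). The mean of 4 keratinised skin genes was 3.81 to 4.11 on the 4 week arrays, below all arrays of 8 weeks (4.47 to 4.71) and 20 weeks (4.54 to 4.83), where the macrophage genes below were also higher. This came from Sbsn, suprabasin, which rose by 2.46 ± 0.53 SE to 8 weeks and 2.63 ± 0.56 to 20 weeks (adjusted p = 0.022 and 0.0149; 1.37 and 1.49 as the mean of its probe sets). The changes of Krt10, Flg and Dsg1a were 0.26, -0.13 and -0.13, and -0.0044, 0.044 and 0.061, and the list did not pass (camera adjusted p = 0.721 and 0.189), nor without any 1 array. Sbsn lost its call to 8 weeks without 4 weeks replicates 2 (0.0738), 3 (0.0784) and 4 (0.0689) and 8 weeks replicates 1 (0.0557) and 3 (0.0548), and to 20 weeks without 4 weeks replicates 2 (0.053) and 4 (0.0692). The 3' minus 5' signal of the actin control probe sets, which grows as RNA degrades, averaged 2.90 ± 0.92 (SD, n = 4), 2.63 ± 0.50 (n = 6), 3.69 ± 0.52 (n = 6), 4.56 ± 1.24 (n = 5) and 3.89 ± 0.89 (n = 5). For the Gapdh control probe sets the same difference averaged 1.62 ± 1.63, 1.15 ± 0.23, 1.80 ± 0.41, 2.03 ± 0.66 and 2.54 ± 0.40. From 16 to 20 weeks it rose while that of actin fell.

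**Figure D1:**
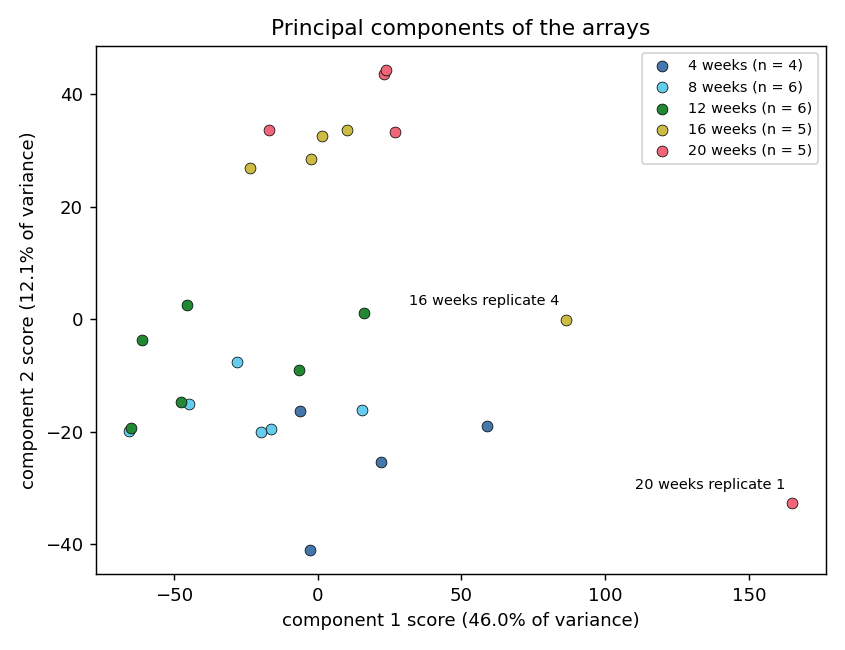
Principal components of the genes kept, 1 point per array coloured by age, with component 1 (46.0% of the variance) on the horizontal and component 2 (12.1%) on the vertical axis. Component 1 followed the SD of all log2 values of an array, with a Pearson r of -0.996. The 16 and 20 week arrays lie at 26.9 to 44.3 on component 2, except the labelled 16 weeks replicate 4 (-0.15) and 20 weeks replicate 1 (-32.7).

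**Figure D2:**
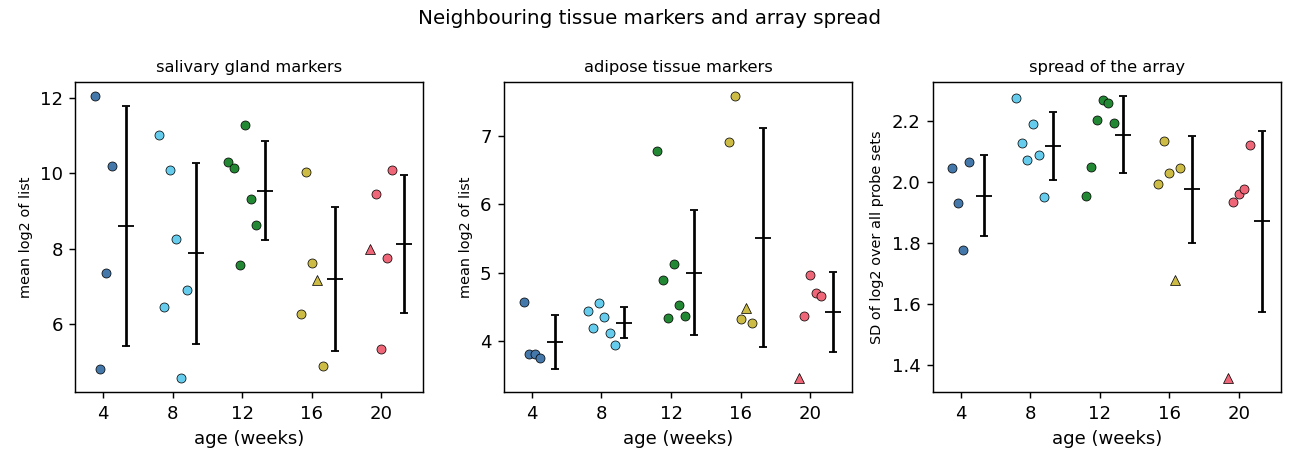
Mean log2 of the salivary gland list, mean log2 of the adipose tissue list and SD of all log2 values, for each array by age in weeks; bars are the mean ± SD of an age and triangles mark the arrays that stood apart. The salivary gland list runs from 4.56 to 12.04, and 16 weeks replicate 2 has the highest adipose tissue value, 7.58.

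Across the 5 ages, 1847 of 12377 genes changed in the limma F test, 1515 of them with at least a 2-fold range between age means. The highest mean fell at 8 weeks for 659 of these genes and at 12 weeks for 719, and the lowest at 20 weeks for 1033. The SD of an array's log2 values was also highest at 8 and 12 weeks, with means of 2.12 and 2.15, and lowest at 20 weeks, at 1.87. With array spread as a covariate 1889 genes passed, 1106 of them among the 1847. The largest F belonged to 5530400C23Rik, a gene model without a descriptive name, at 12.04 ± 1.60 (SD, n = 4) at 4 weeks and 2.80 to 3.09 later (adjusted p = 5.09e-13). Cyp4a12a, a fatty acid hydroxylase known for its high level in male kidney, went from 4.55 ± 0.23 at 4 weeks to 11.43 ± 0.28 (n = 6) at 8 weeks and 9.14 ± 1.46 (n = 5) at 20 weeks. Ly6f, of the Ly6 family of cell surface proteins, went from 4.82 to 11.87 and 11.20. Igha, the constant region of IgA, averaged 6.23, 9.41, 11.60, 10.95 and 11.37 from 4 to 20 weeks. Igkv8-30, a kappa chain variable segment read only by a probe set that can bind related segments, averaged 3.82, 6.76, 8.79, 9.22 and 9.59. Clu, the extracellular chaperone clusterin, averaged 9.89 at 4 weeks and 12.45 at 20 weeks. Cars, the cysteine tRNA synthetase, averaged 6.99 and 4.34 at the same ages. The ubiquitin ligase Rchy1 averaged 7.66 and 5.38, the transporter Slc16a12 6.25 and 4.72, and the mitochondrial thioredoxin Txn2 7.88 and 6.76. Each of these 10 genes passed in every refit without 1 array. Txn2 lost its call with quantile normalization (adjusted p = 0.196, from 1.73e-08 over its alternatives). The number of genes was 2952 without 20 weeks replicate 5, the only array whose absence moved it by over 1.5 times.

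**Figure D3:**
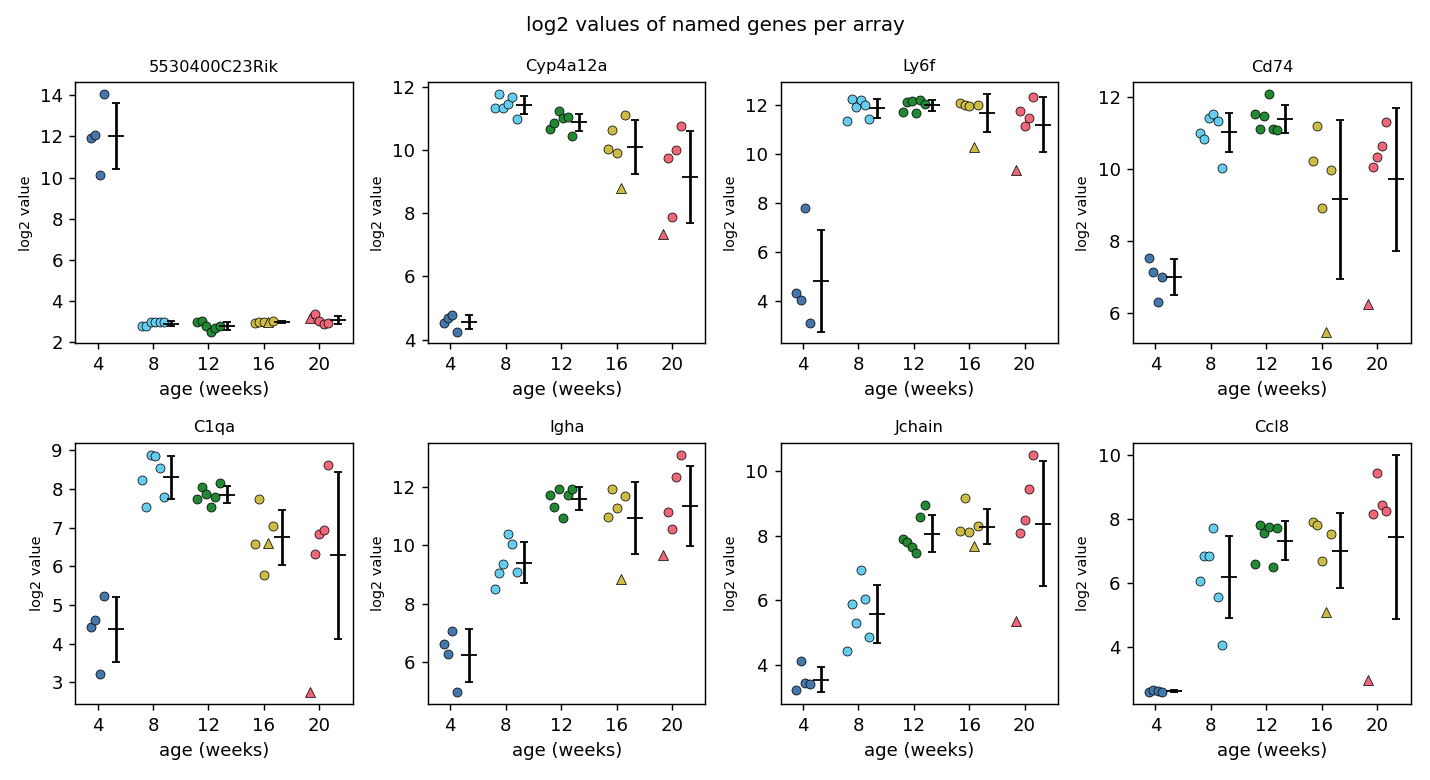
Log2 expression of 8 genes per array by age in weeks; bars are the mean ± SD of an age and triangles mark the arrays that stood apart. 5530400C23Rik falls from 12.04 at 4 weeks to 2.92 at 8 weeks while Cyp4a12a goes from 4.55 to 11.43, and Igha goes from 6.23 at 4 weeks to 11.60 at 12 weeks.

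Between 4 and 8 weeks, before clinical disease, macrophage and antigen presentation genes rose. Of 16 macrophage genes, 8 rose over all genes and 14 adjusted over the list alone, with a mean log2 change of 1.80 and 15 of 16 positive. C1qa (3.93 ± 0.68 SE, adjusted p = 0.00297), C1qc (3.20 ± 0.55, 0.00297) and C1qb (2.53 ± 0.47, 0.00624) encode the C1q protein that starts the classical complement pathway. Lyz2 (3.59 ± 0.52, 0.00066) is the lysozyme of myeloid cells. All 6 arrays at 8 weeks lay above all 4 at 4 weeks for each of these. The change of C1qc is a lower bound, as its 4 week mean lay near background. Of 6 genes of antigen presentation on MHC class II, 5 rose by either count, with a mean of 2.87. They were H2-Ab1 (3.51 ± 0.51, adjusted p = 0.00066), H2-Eb1 (3.87 ± 0.70, 0.00455) and H2-Aa (3.15 ± 0.65, 0.0146), which form the class II molecules. The others were their invariant chain Cd74 (4.02 ± 0.84, 0.0166) and Ctss (2.35 ± 0.52, 0.0247), a protease of the same route named after its values were seen. The chemokine Ccl9 rose by 3.41 ± 0.51 (adjusted p = 0.00078), and so did Igha, by 3.18 ± 0.60 (0.00666).

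Camera placed the macrophage list at an adjusted p of 6.07e-14, with an adjusted p = 0.148 with an estimated correlation and 2.41e-19 at the lowest over its alternatives. For the class II list the adjusted p was 6.1e-08, with an adjusted p = 0.225 with an estimated correlation and 6.06e-17 at the lowest. Both passed without any 1 array. Cd74 lost its call without 4 weeks replicate 2 or 3 (adjusted p = 0.0572 and 0.0809) and H2-Aa without 4 weeks replicate 2 or 4 (0.0593 and 0.0574). Immediate early genes, which respond within minutes to stimuli or handling, rose by a mean of 0.62 in 19 genes (adjusted p = 0.0072, adjusted p = 0.715 with an estimated correlation). Of these 2 rose over all genes and 6 adjusted over the list alone, Fos among them at 2.09 ± 0.31 (adjusted p = 0.000811), a lower bound as its 4 week mean lay near background. The heat shock list was higher by a mean of 0.83 in 14 genes, none over all genes by limma and 2 adjusted over the list alone (adjusted p = 0.01, adjusted p = 0.792 with an estimated correlation). Over 21 alternatives the heat shock mean ran from 0.27 to 0.94 and the immediate early mean from 0.36 to 0.71, with 19 and 20 calls kept. The lists of MHC class I genes (mean 0.92, adjusted p = 0.0159, adjusted p = 0.715 with an estimated correlation), with 2 of 9 rising adjusted over the list alone, and of the type I interferon response (mean 0.63, 0.0104, adjusted p = 0.792 with an estimated correlation), with 1 of 20, were higher too. The class I list lost its call without 4 weeks replicate 1 or 8 weeks replicate 5 (adjusted p = 0.0612 and 0.0607), and the interferon list without 8 weeks replicate 3 or 5 (0.0677 and 0.161). The other list that was higher was oxidative phosphorylation, by a mean of 0.58 in 27 genes (adjusted p = 0.0419, adjusted p = 0.792 with an estimated correlation). T cell genes were lower by a mean of -0.17 in 7 genes, 1 of them above background at 4 or 8 weeks (0.0449, adjusted p = 0.792 with an estimated correlation). The oxidative phosphorylation list lost its call without 4 weeks replicates 2 (0.106) and 3 (0.287, at a mean of 0.35) and 8 weeks replicates 2 (0.086), 3 (0.0831) and 4 (0.0615). The T cell list lost it without 4 weeks replicates 2 (0.0778) and 3 (0.0848) and 8 weeks replicates 1 (0.0819), 2 (0.054) and 5 (0.0607).

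In all, 168 genes changed between 4 and 8 weeks, 141 upwards and 27 downwards, of 1748 at an unadjusted p under 0.05. The higher share, 83.9%, was 61.8% with array spread as a covariate and 58.6% with array weights. Those weights put most of the 4 week mean on replicate 2, at 10.9 against 0.52 to 1.00 for the other 4 week arrays. Large increases were Ly6f at 7.05 ± 0.63 (132-fold, adjusted p = 3.28e-07) and Cyp4a12a at 6.88 ± 0.48 (117-fold, 5.13e-09). Others were Pgf, the placental growth factor (4.74 ± 0.72, 0.000841), the fucosyltransferase Fut4 (4.67 ± 0.72, 0.001) and the cytochrome P450 Cyp2j13 (4.67 ± 0.69, 0.000766). Further ones were Bok of the Bcl-2 family (4.38 ± 0.64, 0.000745), the melanocortin receptor accessory protein Mrap (4.22 ± 0.77, 0.00519) and the lysozyme Lyz1 (4.02 ± 0.52, 0.000187). 5530400C23Rik fell by 9.12 ± 0.39 (adjusted p = 2.92e-13). Fdft1, the squalene synthase of cholesterol synthesis, fell by 1.96 ± 0.35 (0.00455) and Slc16a12 by 1.82 ± 0.15 (1.07e-07). The changes of Pgf, Fut4 and Bok, near background at 4 weeks, and of 5530400C23Rik and Fdft1, near it at 8 weeks, are lower bounds. Each gene described so far in this paragraph differed in the same direction on all 6 arrays at 8 weeks against all 4 at 4 weeks, and passed without any 1 array. They are a selection. Of the 41 called genes that the naming rule picked for this comparison, 24 passed in every such refit and 17 did not. Falls left out above include Cyp39a1 (-2.60, call kept in 20 of 25 alternatives) and Prkaa2 (-1.39, 10 of 25). As the mean of all probe sets of a gene the changes were 2.32 for Fut4, 2.05 for Mrap, 2.66 for Lyz1 and -0.96 for Fdft1. The count was 61, 72 and 87 without 4 weeks replicates 2, 3 and 4, and 88, 106, 93, 68 and 382 without 8 weeks replicates 1, 2, 3, 4 and 6. Without 8 weeks replicate 5, 5 lists passed in place of 8. The number of genes was 604, with all 168 among them, without the arrays that stood apart at 16 and 20 weeks, which enter this contrast through the shared spread.

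**Figure D4:**
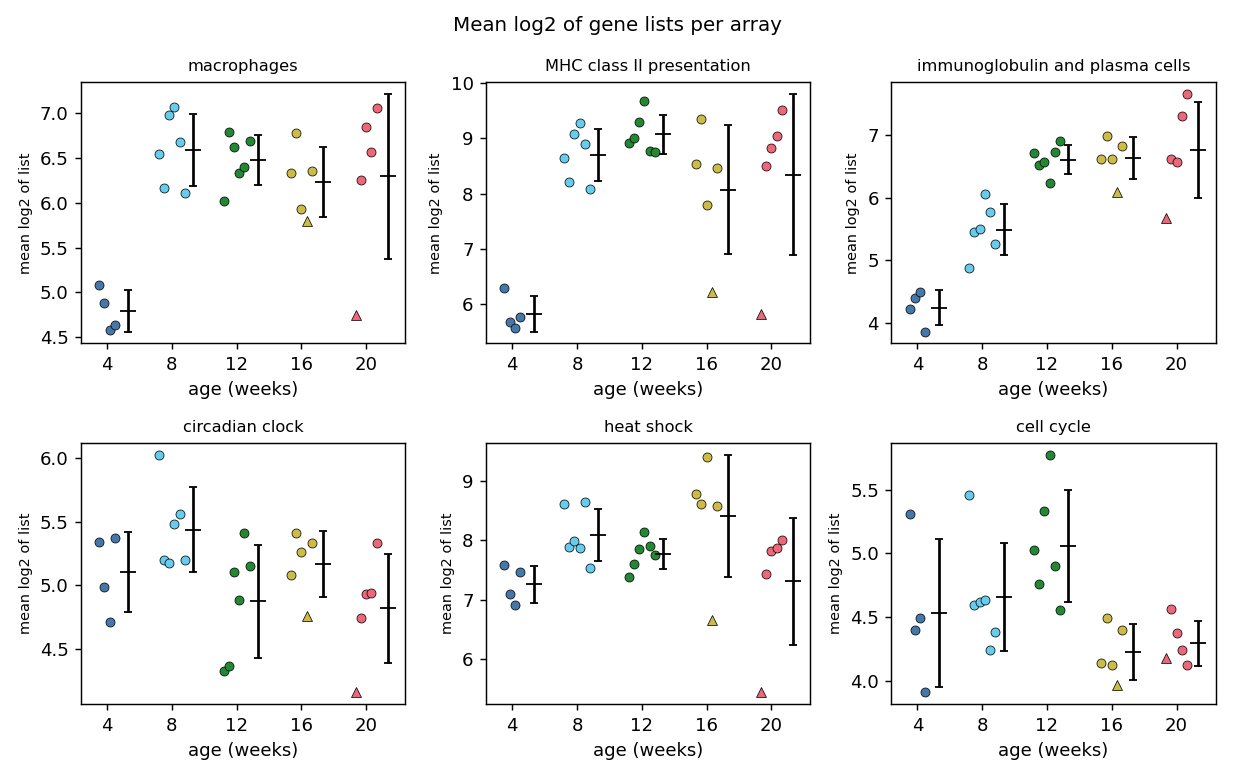
Mean log2 expression of 6 gene lists per array by age in weeks; bars are the mean ± SD of an age and triangles mark the arrays that stood apart. The macrophage list goes from 4.79 at 4 weeks to 6.59 at 8 weeks, the immunoglobulin and plasma cell list from 4.25 at 4 weeks to 6.61 at 12 weeks, and the heat shock list from 8.41 at 16 weeks to 7.31 at 20 weeks.

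Between 8 and 12 weeks, when leukocytes are said to arrive, 2 genes changed by limma, of 614 at an unadjusted p under 0.05. Fads2b, of the fatty acid desaturase family, rose by 2.14 ± 0.32 (adjusted p = 0.0105), higher on all 6 arrays, and Galnt11, which starts O-linked glycosylation, fell by 0.65 ± 0.11 (0.0357), lower on all 6. The antibody genes Jchain, which joins IgA and IgM polymers, and Igha stood 2.48 ± 0.57 and 2.19 ± 0.54 higher on all 6 arrays without passing (adjusted p = 0.171 and 0.248). The immunoglobulin and plasma cell list missed the threshold with 2 of 4 genes rising adjusted over the list alone (mean 1.12, adjusted p = 0.0528). B cell genes rose as a list by a mean of 0.43 (adjusted p = 0.0111, adjusted p = 0.669 with an estimated correlation), and lymphoid chemokine and adhesion genes by 0.35 (0.0191, adjusted p = 0.669 with an estimated correlation). Both rested on single arrays. Without 12 weeks replicate 4, whose means were 5.38 and 5.32, the changes were 0.17 and 0.16 (adjusted p = 0.245 and 0.315). Both also lost their calls without 8 weeks replicate 1 (0.109 for both). The chemokine list lost it without 12 weeks replicates 1 (0.0559) and 2 (0.113), and the B cell list without 12 weeks replicate 1 (0.0826).

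Circadian clock genes fell as a list at 12 weeks, by a mean of -0.56 with 3 of 16 positive (adjusted p = 1.16e-05, adjusted p = 0.177 with an estimated correlation, 1.02e-07 at the lowest over its alternatives). Adjusted over the list alone 1 rose and 5 fell, against none over all genes by limma. Dbp, a transcription factor driven by the clock, was -3.17 ± 0.72 lower, on all 6 arrays, at an adjusted p of 0.168. The fall came mostly from 12 weeks replicates 1 to 4, at 4.26 to 6.96. Replicates 5 and 6 were at 8.99 and 9.02, against 9.31 at the lowest on the 8 week arrays. The type I interferon response fell by a mean of -0.36 (adjusted p = 1.16e-05, adjusted p = 0.669 with an estimated correlation, 4.6e-08 at the lowest). Both lists passed without any 1 array, but without 8 weeks replicate 5 the interferon mean was -0.15 (adjusted p = 0.0345). Fatty acid synthesis genes rose by 0.53 (adjusted p = 0.0112, adjusted p = 0.873 with an estimated correlation) and cell cycle genes by 0.40 (0.0126, adjusted p = 0.895 with an estimated correlation). Heat shock genes fell by a mean of -0.32 (0.0204, adjusted p = 0.895 with an estimated correlation). The first ran from 0.14 to 0.94 over its 23 alternatives, of which 20 kept its call. It lost the call without 12 weeks replicate 1 (0.35, adjusted p = 0.428), the array with the highest adipose tissue mean of its age. The second lost it without 8 weeks replicate 5 (0.0676) and 12 weeks replicates 1 (0.167) and 4 (0.245, at a mean of 0.26). The third lost it without 8 weeks replicates 1 (0.146) and 5 (0.153, at a mean of -0.21) and 12 weeks replicates 1 (0.167) and 2 (0.115). The actin difference was also higher at 12 than at 8 weeks (2.63 and 3.69), and with it as a covariate 13 lists passed in place of 7, with 5 in common. The circadian clock list was then at -0.50 (adjusted p = 5.84e-05), the type I interferon response list at -0.23 (0.00312), fatty acid synthesis at 0.94 (7.69e-06), B cells at 0.44 (0.026) and lymphoid chemokines and adhesion at 0.40 (0.0334). Cell cycle and heat shock did not pass, at 0.30 ± 0.25 and -0.08 ± 0.45 (SE of the list mean; 0.5 and 0.249) in place of 0.40 ± 0.22 and -0.32 ± 0.41. Fads2b kept its call without any 1 array and lost it with the tissue markers or actin as covariates, with changes of 2.05 and 2.02 in place of 2.14 (adjusted p = 0.0761 and 0.112). The median SE of the 2 genes was then 0.236 and 0.243 in place of 0.215. With replicate numbers as a block Fads2b lost its call at 2.14 (0.0669). Galnt11 lost it without 8 weeks replicates 1 (0.0942), 2 (0.0682), 3 (0.0611), 4 (0.0697) and 5 (0.105) and 12 weeks replicates 2 (0.0649), 3 (0.124) and 6 (0.102). The number of genes was 1 without 8 weeks replicates 1, 3 or 5 or 12 weeks replicates 3 or 6, 7 without 12 weeks replicate 1, 5 without 12 weeks replicate 4, and 8 without the arrays that stood apart at later ages. For lists, 2 passed without 12 weeks replicate 1. The higher share was 50% and became 100% of 1 gene after centring.

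Between 12 and 16 weeks, the step to clinical disease, 369 genes changed, 325 downwards and 44 upwards, of 2583 at an unadjusted p under 0.05. Genes of proliferation fell. Cdt1, which licenses DNA replication, fell by 3.17 ± 0.62 (adjusted p = 0.0121). The thymidine kinase Tk1 fell by 1.64 ± 0.32 (0.0121) and the proliferation marker Mki67 by 2.86 ± 0.68 (0.03), all of them below all 6 arrays of 12 weeks on all 5 arrays. Of 27 cell cycle genes, 5 fell over all genes and 10 adjusted over the list alone (mean -0.83, camera adjusted p = 0.0343, adjusted p = 0.862 with an estimated correlation). The 5 were Tk1, Mki67, Cdc20 (-2.25 ± 0.54), Mcm7 (-2.57 ± 0.66) and Cdk1 (-2.01 ± 0.53), the last named after its values were seen. Other large decreases were Col7a1, the collagen of anchoring fibrils (-3.37 ± 0.52, adjusted p = 0.00514), the splicing factor Srsf5 (-3.04 ± 0.53, 0.0118), the deubiquitinase Mindy2 (-2.47 ± 0.46, 0.0121) and Aamp, a gene of the Idd5 region list (-2.02 ± 0.37, 0.0118). Per2, a core clock repressor, rose by 1.31 ± 0.24 (adjusted p = 0.0118) on all 5 arrays. Of 16 clock genes 3 rose over all genes and 4 adjusted over the list alone, and the list as a whole did not pass (mean 0.29, adjusted p = 0.27). The other risers were Usp2 (2.67 ± 0.67) and Cry1 (1.01 ± 0.25), a deubiquitinase with a daily rhythm and a clock repressor. Abtb2 rose by 1.73 ± 0.34 (adjusted p = 0.0121). The changes of Cdt1, Tk1 and Cdk1 are lower bounds, as their 16 week means lay near background.

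Heat shock genes rose as a list at 16 weeks, by a mean of 0.64 in 14 genes (adjusted p = 0.00828, adjusted p = 0.862 with an estimated correlation). Over all genes 2 rose, Hspa1a (1.74 ± 0.46) and Hspa4l (0.79 ± 0.19), and 6 adjusted over the list alone. Both changes are lower bounds, from 12 week means near background. The unfolded protein response list, of chaperones, stress sensors, transcription factors and degradation genes, fell by a mean of -0.83, 2 of 28 genes by either count (adjusted p = 0.00828, adjusted p = 0.862 with an estimated correlation). These were Pdia6 at -2.01 ± 0.39 (adjusted p = 0.0121) and Dnajb11 at -1.37 ± 0.37 (0.0478). Oxidative phosphorylation fell by a mean of -0.84, none of 27 genes over all genes (limma, adjusted p = 0.00828, adjusted p = 0.862 with an estimated correlation). Without 16 weeks replicate 4 alone these means were -0.40 and -0.36 (adjusted p = 0.117 and 0.145), and without both arrays that stood apart the adjusted p was 0.097 and 0.0845. Over the 22 alternatives these means ran from -0.98 to -0.18 and from -1.06 to -0.07, with 17 and 16 calls kept. The cell cycle list lost its call without 12 weeks replicates 1 (0.118), 2 (0.0742) and 4 (0.0598) and 16 weeks replicate 2 (0.0741), and the heat shock list without 12 weeks replicate 1 (0.0515). The heat shock mean was 0.39 without 16 weeks replicate 3 (adjusted p = 0.0298) and 1.07 without 16 weeks replicate 4 (7.15e-06), and without the former Hspa4l was 0.50 (0.0331).

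At this step the actin difference stood higher (3.69 to 4.56), and so did the adipose tissue mean, by 0.51 (camera adjusted p = 0.164; -0.0099, 0.16, 0.77, 0.80, 0.82 and 0.86 without 16 weeks replicates 2, 1, 4, 3 and 5 and 12 weeks replicate 1), while the salivary gland mean was -2.35 lower (camera adjusted p = 0.27). With both tissue means as covariates 2 genes passed in place of 369. All 369 kept their direction, their median size went from 1.32 to 1.17 and their median SE from 0.316 to 0.354, so that the median adjusted p went from 0.0328 to 0.219. With actin as a covariate 116 passed, with all 369 in the same direction, a median size of 1.25, a median SE of 0.334 and a median adjusted p of 0.0724. Abtb2, Col7a1, Cdt1, Srsf5, Mindy2, Tk1, Pdia6, Per2 and Aamp passed without any 1 array. As the mean of their probe sets Cdt1 was -1.11, Mindy2 -1.45, Pdia6 -0.98, Abtb2 0.65 and Per2 0.45. Of the 33 called genes that the naming rule picked for this step, 10 passed in every refit without 1 array and 23 did not. As the mean of their probe sets Cdt1 was -1.11, Mindy2 -1.45, Pdia6 -0.98, Abtb2 0.65 and Per2 0.45. Mki67 lost its call without 12 weeks replicates 3 (0.0731), 4 (0.085) and 5 (0.0527) and 16 weeks replicates 1 (0.0814), 3 (0.0715) and 4 (0.0592). Cdc20 and Mcm7 lost theirs without the same 6 arrays (0.0605 to 0.0868 and 0.0703 to 0.112), Mcm7 also without 16 weeks replicate 5 (0.0509). Both lost it without probe sets that can bind related transcripts (-1.41, adjusted p = 0.117, and -0.82, 0.189). Usp2 and Cry1 lost theirs without 12 weeks replicates 4 to 6 and 16 weeks replicates 1, 2, 3 and 5 (0.0524 to 0.0832 and 0.06 to 0.0868), Usp2 also without 16 weeks replicate 4 (0.0563) and Cry1 without 12 weeks replicate 3 (0.0673). Hspa4l and Dnajb11 lost theirs without 12 weeks replicates 3 to 6 and 16 weeks replicates 1 and 4 (0.0537 to 0.0783 and 0.0692 to 0.126), Dnajb11 also without 16 weeks replicates 3 (0.0714) and 5 (0.0556). Hspa1a lost its call without any of 9 arrays, all but 12 weeks replicate 1 and 16 weeks replicate 4 (0.0522 to 0.114). The count was 886, 100, 68, 110 and 170 without 12 weeks replicates 1, 3, 4, 5 and 6, and 94, 82, 123 and 177 without 16 weeks replicates 1, 3, 4 and 5. For lists, 2, 9, 2 and 7 passed without 12 weeks replicate 1 and 16 weeks replicates 3, 4 and 5. The higher share, 11.9%, was 53.7% of 503 genes after quantile normalization, 63.9% with array spread as a covariate and 33.5% of 501 genes without the arrays that stood apart.

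Between 16 and 20 weeks, to the onset of secretory dysfunction, 2 genes changed by limma, of 1008 at an unadjusted p under 0.05. Rnf216, a ubiquitin ligase, rose by 1.63 ± 0.27 (adjusted p = 0.0267), above all arrays of 16 weeks on 4 of 5, a lower bound as its 16 week mean lay near background. Thap1, a zinc finger transcription factor, fell by 0.57 ± 0.09 (0.0185), below them on all 5. Heat shock genes fell as a list, by a mean of -1.10 with none of 14 positive (adjusted p = 3.4e-07, adjusted p = 0.713 with an estimated correlation, 1.28e-15 at the lowest over its alternatives). Adjusted over the list alone 6 fell, against none over all genes by limma. Hsph1 and Dnaja1, chaperones of the cytosol, were -3.05 ± 0.63 and -1.65 ± 0.42 lower on all 5 arrays (adjusted p = 0.147 and 0.324). This list passed without any 1 array, with a mean of -0.63 without 20 weeks replicate 1 (adjusted p = 4.6e-06). The unfolded protein response fell by a mean of -0.47 (adjusted p = 0.00442, adjusted p = 0.738 with an estimated correlation) and oxidative phosphorylation by -0.43 (0.00734, adjusted p = 0.798 with an estimated correlation). Without 20 weeks replicate 1 the means were -0.01 and 0.13 (adjusted p = 0.23 and 0.699). Without 16 weeks replicate 4 they were -0.90 and -0.91 (1.99e-07 for both), and the second was -0.64 without 20 weeks replicate 5 (0.00229). Fatty acid oxidation fell by a mean of -0.55 (adjusted p = 0.00734, adjusted p = 0.713 with an estimated correlation) and fatty acid synthesis by -0.66 (0.0162, adjusted p = 0.713 with an estimated correlation). Over 21 alternatives these 2 means ran from -0.70 to -0.27 and from -0.92 to -0.13, with 16 and 15 calls kept. The adipose tissue mean was -1.08 lower (adjusted p = 0.0539; -0.56 without 16 weeks replicate 2).

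Without 16 weeks replicate 1 or 2, the arrays highest in adipose tissue genes, the adjusted p was 0.0874 and 0.0668 for fatty acid oxidation, 0.14 and 0.113 for fatty acid synthesis and 0.0874 and 0.113 for oxidative phosphorylation. Fatty acid synthesis also lost its call without 20 weeks replicate 3 (0.0528). Without 16 weeks replicate 2 the means were -0.35, -0.41 and -0.21, and without 20 weeks replicate 1 fatty acid synthesis was -0.41 (0.00963). Rnf216 lost its call without 16 weeks replicates 1 to 5 (0.071, 0.0963, 0.0567, 0.06 and 0.117) and 20 weeks replicates 2 to 5 (0.15, 0.0763, 0.104 and 0.0607). Thap1 lost its call without 16 weeks replicates 2 (0.0547), 3 (0.0567) and 5 (0.0928) and 20 weeks replicates 2 (0.0857) and 4 (0.0811). The number of genes was 0 by limma without 16 weeks replicates 2, 3 or 5 or 20 weeks replicates 2 or 4, 1 without 16 weeks replicate 1, 12 without 20 weeks replicate 1, 4 without 20 weeks replicate 5 and 10 without both arrays that stood apart. For lists, 2, 3, 11 and 10 passed without 16 weeks replicates 1, 2 and 4 and 20 weeks replicate 1. The higher share, 50% here, was 28.3% of 46 genes after quantile normalization and 0% of 1 gene after centring.

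Over the whole course, from 4 to 20 weeks, antibody, complement, macrophage and antigen presentation genes rose. The macrophage, class II and complement list means were 4.79, 5.83 and 3.98 at 4 weeks and 6.59, 8.70 and 4.84 at 8 weeks. At 20 weeks they were 6.30, 8.34 and 4.98, so most of their rise came by 8 weeks. The 20 week means are drawn down by replicate 1, at 4.74, 5.82 and 4.14. The other 20 week arrays lay at 6.26 to 7.06, 8.51 to 9.51 and 4.81 to 5.42. The lower macrophage and class II means at 20 than at 8 weeks therefore rest on that array. The immunoglobulin and plasma cell list went from 4.25 to 5.49 at 8 weeks and 6.61 at 12 weeks, and was at 6.76 at 20 weeks. Igha rose by 5.14 ± 0.62 (adjusted p = 5.1e-05), Jchain by 4.82 ± 0.67 (0.00038), Igk, the kappa locus, by 5.18 ± 1.03 (0.0108) and Igkv8-30 by 5.78 ± 0.67 (2.43e-05), all above every 4 week array on all 5 arrays. The immunoglobulin and plasma cell list rose by a mean of 2.51, 2 of 4 genes by either count (adjusted p = 0.000347, adjusted p = 0.00972 with an estimated correlation, 0.134 on ranks). Complement rose by a mean of 1.00, 2 of 13 genes over all genes and 6 adjusted over the list alone (1.56e-05, adjusted p = 0.00972 with an estimated correlation), which passed in all 20 alternatives. The complement genes were C1qb (2.81 ± 0.49, adjusted p = 0.00345) and C1qc (2.60 ± 0.57, 0.0196), also counted among the macrophage genes. Of those, 7 of 16 rose over all genes and 11 adjusted over the list alone (adjusted p = 1.87e-11, adjusted p = 0.0938 with an estimated correlation). Of 6 class II genes, 4 rose over all genes and 5 adjusted over the list alone (mean 2.51, adjusted p = 3e-07, adjusted p = 0.12 with an estimated correlation): H2-Ab1 (3.08 ± 0.53), H2-Aa (3.25 ± 0.67), H2-Eb1 (3.06 ± 0.72) and Ctss (2.57 ± 0.55). Inflammatory chemokines and cytokines rose by a mean of 0.83 (adjusted p = 0.00229, adjusted p = 0.0938 with an estimated correlation), 2 of 15 by either count, Ccl8 (4.84 ± 0.91) and Ccl9 (3.45 ± 0.53), which attract monocytes and other leukocytes. The changes of Jchain, Igk, Igkv8-30, C1qc and Ccl8 are lower bounds, as their 4 week means lay near background.

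Interferon gamma response genes rose by a mean of 0.60, none of 12 over all genes by limma and 3 adjusted over the list alone (adjusted p = 0.00242, adjusted p = 0.648 with an estimated correlation). Type I interferon genes rose by 0.43 (0.0136, adjusted p = 0.688 with an estimated correlation) and lymphoid chemokine and adhesion genes by 0.48 (0.0324, adjusted p = 0.546 with an estimated correlation). Further increases were Lcn2, the iron-binding lipocalin of inflamed epithelium (4.14 ± 0.73, adjusted p = 0.0035), and the protease inhibitor Mug1 (4.20 ± 0.71, 0.00269). The lists that fell were the unfolded protein response (mean -0.78, adjusted p = 0.000246, adjusted p = 0.688 with an estimated correlation), oxidative phosphorylation (-0.56, 0.00452, adjusted p = 0.81 with an estimated correlation), fatty acid oxidation (-0.62, 0.00483, adjusted p = 0.546 with an estimated correlation). So did extracellular matrix (-0.46, 0.00763, adjusted p = 0.688 with an estimated correlation) and cholesterol synthesis (-0.59, 0.00846, adjusted p = 0.437 with an estimated correlation). Over all genes, 2 of 28, 2 of 27, none of 15, 1 of 19 and 1 of 16 members fell, and adjusted over the list alone 5, 3, 4, 4 and 2. They included Fdft1 (-2.03 ± 0.37, adjusted p = 0.00475) and the main chain of type I collagen, Col1a1 (-1.06 ± 0.23, 0.016). Slc16a1, a lactate and pyruvate transporter, fell by 2.90 ± 0.42 (adjusted p = 0.000625), Cars by 2.65 ± 0.39 (0.000625). Uso1, a vesicle tether between endoplasmic reticulum and Golgi, fell by 2.62 ± 0.51 (0.00823), and Cyp39a1, which hydroxylates 24-hydroxycholesterol, by 3.09 ± 0.58 (0.00674). The changes of Mug1, near background at 4 weeks, and of Fdft1 and Cyp39a1, near it at 20 weeks, are lower bounds.

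In all, 273 genes changed over the course, 111 upwards and 162 downwards, of 1813 at an unadjusted p under 0.05. With only the arrays of 4 and 20 weeks in the fit 4 genes passed, and each gene named here for this comparison lost its call. The main fit, whose SEs are given here, takes the spread of a gene from all 26 arrays. At 20 weeks the SD was 1.38 for Igha and 1.85 for Igkv8-30, the highest of the 5 ages for both. The cause of the lost calls was not tested. Without the arrays that stood apart 1021 genes passed, 720 of them upwards and 267 of them among the 273. The unfolded protein response then had a mean of -0.32 (adjusted p = 0.11) and oxidative phosphorylation -0.0041 (0.733), and fatty acid oxidation -0.45 (0.0618). Col1a1 lost its call without 4 weeks replicates 1 (0.056) and 4 (0.0529). C1qc lost it without 4 weeks replicate 2 (0.0709) and 20 weeks replicates 3 (0.0568) and 4 (0.0611), and Ctss without 4 weeks replicate 2 (0.0612). H2-Aa lost it without 4 weeks replicates 2 (0.0529) and 4 (0.0644), and H2-Eb1 without 4 weeks replicates 2 (0.105) and 4 (0.0902) and 20 weeks replicates 2 (0.0556), 3 (0.0718) and 4 (0.0753). The rest of the genes named in these paragraphs on the whole course passed in all 9. Not every gene picked is named there. Of the 43 called genes that the naming rule picked for this comparison, 18 passed in all 9 and 25 did not. H2-Ab1 did not pass without probe sets that can bind related transcripts (1.36, adjusted p = 0.337) or as the mean of its probe sets (1.65, 0.097). As that mean Igk was 1.32, Slc16a1 -1.45, Cars -1.33 and Fdft1 -0.98. Without 4 weeks replicate 1 the adjusted p was 0.709 for extracellular matrix, 0.0536 for cholesterol synthesis, 0.105 for fatty acid oxidation and for oxidative phosphorylation. Without 20 weeks replicate 1 it was 0.124 for extracellular matrix and the unfolded protein response and 0.618 for oxidative phosphorylation. Without 20 weeks replicate 5 it was 0.0584 for type I interferon. The extracellular matrix mean was -0.12 and -0.20 without 4 weeks replicate 1 and 20 weeks replicate 1, the oxidative phosphorylation mean -0.33 and -0.0041, and without the latter array the unfolded protein response mean was -0.32. Lymphoid chemokines lost their call without 4 weeks replicates 1 (0.101) and 3 (0.0713) and 20 weeks replicates 1 (0.124), 3 (0.0634) and 5 (0.0584). The count was 73, 411 and 75 without 4 weeks replicates 2, 3 and 4 and 722, 157, 126 and 103 without 20 weeks replicates 1 to 4. For lists, 8 passed without 4 weeks replicate 1 in place of 13.

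Genes tied to this model or to Sjögren's syndrome were also followed. Il2 and Slc11a1, candidate genes of the NOD regions, averaged 3.31 to 3.49 and 2.95 to 3.06 over the 5 ages, and Ctla4 3.22 to 3.35, all close to the array medians. Trim21, the Ro52 autoantigen, averaged 3.05 to 3.58. Aqp5, the water channel of acinar cells, averaged 10.41, 10.90, 11.29, 9.62 and 10.20. Its difference of -1.67 ± 0.77 from 12 to 16 weeks did not pass (adjusted p = 0.217; below all 12 week arrays on 4 of 5). None of these 5 genes passed in any pairwise comparison by limma. The kept genes of the Idd3 and Idd5 lists, 4 and 12, did not pass as lists in any comparison. Aamp was the 1 Idd5 member that fell over all genes at 16 weeks. It was also called lower from 4 to 20 weeks, at -2.14 to -1.43 over 24 alternatives, of which 18 kept the call. Il21, Icos and Chrm3 were not analysed here, as they did not meet the filter.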

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

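The tests of lymphoid tissue, of acinar cell loss, of the arrays that stood apart and of the time of day were chosen only after the results were seen. In groups of 4 to 6 arrays a value was picked out where its gap to the nearest other array exceeded Dixon's 95% limit, which chance does in about 1 in 20 groups. Of 235 groups of gene list means 32 had such an array, and of 495 groups of 99 named genes 52. The lists were 11 for 20 weeks replicate 1, 7 for 16 weeks replicate 4, 4 for 8 weeks replicate 1, 3 for 12 weeks replicate 4, 2 for 4 weeks replicate 1, and 1 each for 8 weeks replicate 6, 12 weeks replicates 1 and 2, 16 weeks replicate 2 and 20 weeks replicate 4. The named genes were 18 for 20 weeks replicate 1, 10 for 16 weeks replicate 4, 5 for 8 weeks replicate 6, 4 for 4 weeks replicate 1, 3 each for 4 weeks replicate 3 and 12 weeks replicate 1, 2 each for 16 weeks replicate 3 and 20 weeks replicate 4, and 1 each for 4 weeks replicate 4, 8 weeks replicate 1, 12 weeks replicate 5, 16 weeks replicate 1 and 20 weeks replicate 5. Among array measures, 20 weeks replicate 1 had an SD of 1.36, and the median correlation with the own age was 0.869 for that array and 0.921 for 16 weeks replicate 4. The 3' 18S control probe set was at 4.13 on 8 weeks replicate 3, 8.12 on 12 weeks replicate 3 and 6.40 on 20 weeks replicate 4, apart from its age on each. Of 9160 probe sets without a gene here, 3908 passed the filter and 128 changed across the ages in the limma F test.

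Age labels were exchanged between arrays in 100 splits per comparison, the real split among them. By a rule set beforehand, a share of splits with as many genes under 0.05 counted against chance. Only the real split gave as many genes across all ages (1 of 100, with 1847 against at most 100). The same held for 8 against 4 weeks (1 of 100, 168 against at most 34) and for 16 against 12 weeks (1 of 100, 369 against at most 23). Chance is thus unlikely there, though 100 splits cannot exclude it. For 20 against 4 weeks 4 of 100 splits gave as many as the 273 genes. By the rule that share goes against chance. Another split gave 1076 genes, however, so the real ages were not the extreme grouping and chance is not excluded there. That split points to a structure of the samples besides age. For 12 against 8 weeks 19 of 100 splits, and for 20 against 16 weeks 8 of 100, gave as many as the 2 genes, so chance is not excluded. Other splits reached 377 and 36 genes, which also points to a structure of the samples.

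The higher macrophage and class II genes at 8 than at 4 weeks had list medians of 1.63 and 3.33. Lymphoid tissue caught in the dissection would bring T and B cell genes along, and the higher of those medians was -0.13 (B cells). The means of both lists lay near background. Of 7 T cell and 5 B cell genes, 1 and 2 lay above it at 4 or 8 weeks, with median changes of -0.38 and -0.19. These run against lymphoid tissue but are too few to exclude it, so it stays open. A loss of acinar cells would raise the other cell types alike. The 13 endothelium, fibroblast and nerve genes above background at 4 or 8 weeks had a median of -0.12 (SD over genes 1.17), with Fap the highest at 3.52. Differences in array spread would take the change away, and with spread as a covariate the macrophage median was 1.34. The tests of cell loss and of spread went against those explanations for the macrophage genes, whose median alone was tested. For spread, 1.34 of 1.63 lay only a little above the share set beforehand. The class II list was not put to these tests. Over its 21 alternatives, array spread as a covariate among them, its mean change was 2.19 at the lowest. Beside lymphoid tissue, myeloid cells may enter or activate between 4 and 8 weeks, a hypothesis found and tested on the same data. Normal growth of the gland with age stays open, as no control strain was analysed here.

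Lower oxidative phosphorylation and unfolded protein response genes at the later ages may come in part from the arrays that stood apart. Without them, the mean changes from 12 to 16 weeks were -0.36 in place of -0.84 and -0.40 in place of -0.83 (adjusted p = 0.0845 and 0.097). From 4 to 20 weeks they were -0.0041 in place of -0.56 and -0.32 in place of -0.78 (0.733 and 0.11), as these arrays as a cause would give. From 16 to 20 weeks both lists still passed without them, at -0.36 and -0.44 (adjusted p = 0.000579 and 1.3e-05), which goes against these arrays as the whole cause. There, however, leaving out 20 weeks replicate 1 alone gave 0.13 and -0.01 (0.699 and 0.23). Settings that kept both arrays could shrink the changes from 12 to 16 weeks further than leaving them out, to -0.07 and -0.18 at the least. The 3' minus 5' actin difference was 5.71 on 16 weeks replicate 4, the highest of all arrays, and 4.97 on 20 weeks replicate 1. It was also 5.60 on 16 weeks replicate 3, which did not stand apart. The Gapdh difference was 1.62 on 16 weeks replicate 4, below its age mean of 2.03 and below replicate 3 (2.80). On 20 weeks replicate 1 it was 3.08, the highest of that age. Its highest value of all arrays was 3.83, on 4 weeks replicate 1. Whether the arrays that stood apart carry poorer RNA or sicker glands was not tested.

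The clock genes may differ because glands were collected at another time of day. That would move genes in phase with Dbp against genes in the opposite phase, and the difference between their mean changes was -1.22 from 8 to 12 weeks (10 genes at -0.90, 4 at 0.32; exact permutation p = 0.00216) and 0.89 from 12 to 16 weeks (0.61 and -0.28; exact permutation p = 0.0216). Cry1, of the opposite phase, went against this from 12 to 16 weeks, when it rose by 1.01 ± 0.25 (adjusted p = 0.0319), and so did Nr1d1, in phase with Dbp, at -0.68 ± 0.47 (0.394). Both comparisons share the 12 week arrays, so opposite signs arise partly from that. Those arrays differed among themselves, with Dbp at 4.26 to 6.96 on replicates 1 to 4 and 8.99 and 9.02 on replicates 5 and 6. With array spread as a covariate the list means were -0.63 (-0.56 without it) and 0.61 (0.29), which goes against array spread as the cause. With actin the first was -0.50. A change of the clock with age or disease stays open and was not tested.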

How the results depend on the processing

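The fits without the arrays that stood apart, with covariates and with gene by gene array weights were chosen after seeing the data. None of the 131 gene calls turned direction in the alternatives run on them. Of 37 list calls, 2 held with an estimated correlation, 28 with quantile normalization, 30 without the arrays that stood apart, 28 with tissue markers, 30 with actin and 26 with array spread as covariates. Of 131 gene calls, 122 held with quantile normalization, 87 with tissue markers, 95 with actin, 103 with replicate numbers as a block and 129 without those arrays. With only the arrays of the ages compared, 53 of 121 gene calls held. Numbers of genes that moved by over 1.5 times follow, with the cause not tested except where fewer arrays or genes entered. With array weights, whose estimation stopped before converging, they were 8152 across the ages, 4557 for 8 against 4 weeks, 142 for 12 against 8, 2795 for 16 against 12, 249 for 20 against 16 and 3473 for 20 against 4. Estimated gene by gene they were 7382, 2686, 148, 2781, 219 and 2709. Both sets of weights put most of the 4 week mean on replicate 2. Its weight was 10.9, against 0.52, 0.57 and 1.00 for the other 4 week arrays, and 5.27 gene by gene. Without the arrays that stood apart, 2 lists passed for 16 against 12. The numbers of genes were then 604 for 8 against 4 and 8 for 12 against 8. They were 10 for 20 against 16 (13 lists) and 1021 for 20 against 4 (8 lists). With array spread they were 21 for 12 against 8, 756 for 16 against 12 (2 lists), 46 for 20 against 16 and 1091 for 20 against 4. With tissue markers they were 1172 across the ages, 0 by limma for 12 against 8, 2 for 16 against 12, 5 for 20 against 16 and 155 for 20 against 4, with 5 lists for 8 against 4 and 7 for 16 against 12. With actin they were 1100, 0, 116, 1 and 176, with 13 lists for 12 against 8. Quantile normalization gave 8 for 12 against 8, 46 for 20 against 16 (1 list) and 852 for 20 against 4, and centring 1, 1 and 178. With no filter 201 passed for 16 against 12 and 163 for 20 against 4, and 9 lists for 20 against 16. For 12 against 8 and 20 against 16 the stricter filter gave 1 and 1, the mean of probe sets 10 and 1, and a 2-fold threshold 1 and 1; without _x_at and _s_at probe sets 4 passed for 12 against 8, and with trend and robust 1 for 20 against 16. With only the arrays of the ages compared, 4 passed for 12 against 8 and 4 for 20 against 4. With an estimated correlation 0 lists passed for each pair of successive ages and 2 for 20 against 4, by camera. Replicate numbers do not pair the arrays: 14 of 47 same-numbered pairs correlated above 0.1, with a median of -0.08, and 2 of 26 arrays correlated best with their own number. As a block they gave 93 genes for 8 against 4, 1 for 12 against 8, 228 for 16 against 12, 0 by limma for 20 against 16 (1008 at an unadjusted p under 0.05 without the block) and 165 for 20 against 4. Leaving out 1 array gave 1380 to 2952 genes across the ages, then in order of the comparisons 61 to 382, 1 to 7, 68 to 886, 0 to 12 and 73 to 722 genes, and 5 to 12, 2 to 10, 2 to 9, 2 to 11 and 8 to 15 lists; 356 of 1464 gene calls and 58 of 375 list calls were lost. The oxidative phosphorylation list turned direction with array spread, to -0.12 for 8 against 4 weeks (adjusted p = 0.586) and 0.027 for 20 against 16 (0.365), and without 20 weeks replicate 1, to 0.13 for 20 against 16 (0.699), where leaving out 1 array gave -0.91 to 0.13.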

Other observations

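Leaving out each array was planned, but its values for these lists were drawn up only after the results with all arrays were seen. Genes of tear secretion did not change as lists with all arrays. The 17 acinar products had a mean change of -0.85 from 12 to 16 weeks, 3 of them above 0 (camera adjusted p = 0.0598), and -0.43 without 16 weeks replicate 4 (0.186). This list passed without 12 weeks replicate 4 (0.0444) and without 16 weeks replicates 1 (0.046), 3 (0.0298) and 5 (0.0176). From 4 to 20 weeks its mean change was -0.30 (0.756), and 0.19 without 20 weeks replicate 1 (0.329). Ltf, the iron-binding lactoferrin of tears, rose from 4 to 8 weeks by 1.84 ± 0.41 SE (adjusted p = 0.0241), above all 4 week arrays on all 6. It lost this call without 4 weeks replicates 1 (0.074), 2 (0.0507) and 3 (0.0878) and 8 weeks replicates 1 (0.0597), 4 (0.0569) and 5 (0.0503). The 9 ductal genes had a mean change of -0.77 from 12 to 16 weeks, all below 0 (adjusted p = 0.0857). It was -0.41 without 16 weeks replicate 4 (0.186), and the list passed without 16 weeks replicate 3 (-0.86, 0.0385). The 20 genes of secretagogue signalling and ion transport, which drive fluid secretion, did not pass in any comparison with all arrays. They passed from 16 to 20 weeks without 20 weeks replicate 1, at 0.40 in place of 0.17 (0.00604).

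Germinal centre B cell, neutrophil and skeletal muscle genes, 5, 3 and 6 in number, did not pass in any comparison, with all arrays or without any 1. From 4 to 20 weeks the adjusted p with all arrays was 0.337, 0.631 and 0.879.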
